A study of Homo sapiens with 8 samples.

How the data were processed

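RNA was sequenced from H9 cells, an established human embryonic stem cell line, that carried a non-targeting short hairpin (shNT) or a hairpin against DAP5 (shDAP5), the protein encoded by EIF4G2. Per the labels' protocols, cells were kept on inactivated mouse embryonic fibroblasts and then grown for 1 passage on Matrigel in conditioned medium. They were treated with cycloheximide, which holds ribosomes on mRNA, at 100 µg/ml for 10 min before lysis, and 12 OD units of lysate were spun through a 10 to 50% sucrose gradient collected in 0.5 ml fractions. Polyadenylated RNA of whole lysate (total RNA) and of the pooled heavy polysome fractions was made into libraries with a TruSeq RNA kit, which does not mark strand, and all 8 libraries shared 1 lane of a HiSeq 2000. The labels name 4 groups of 2 libraries, 1 from passage 51 (replicate a) and 1 from passage 53 (replicate b).

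The deposited table gave 18487 gene symbols in 8 columns, each matched to its sample by hairpin, fraction and replicate letter. Its unit was a signal that is never negative: the deposited values were gene read counts divided by 1 factor per library. Every value of a column was a whole multiple of what 1 read was worth there, so whole reads were recovered for 100% of values within a tolerance of 0.01. The factors equalled median-of-ratios size factors over the 8 libraries (ratio 1). The submitters' processing notes name the hg19 build, TopHat 1.3.3, Partek and DESeq2 1.2.8 without their roles, and the gene annotation and counting rule were not given in the sources used here. Genes that overlap, or that have near-identical copies, are uncertain for that reason. GC content and coding length came from GENCODE and RefSeq annotation of another build, matched by symbol for 95.61% of tested genes, and no coordinate was taken from it. The table is relative, since every library was scaled to the others, so a change of all mRNAs together could not be seen.

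The recovered reads per library ranged from 5165907 (shDAP5 polysome, passage 51) to 19094260 (shDAP5 polysome, passage 53). In the shallowest library the filter described here stood at 8.564 reads and in the deepest at 32.71 reads. PCR copies were not marked, so counting error is a lower limit of the technical error.

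The groups, lists, rule for naming genes, tests and other settings were fixed before the data were examined. Values were analysed as log2(value + 1) for 12387 genes with a mean of at least 20 over the 8 libraries, with limma 3.58.1 in R 4.3.3 (trended eBayes). All 8 libraries entered 1 model of 4 groups with 4 residual and 9.83 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. The contrasts were shDAP5 against shNT in total RNA, the same in heavy polysomal RNA, their difference (the interaction, called loading), and heavy polysomal against total RNA in shNT cells. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. A call means an adjusted p under 0.05. Because the interaction rests on few libraries, a size rule was fixed beside it: genes with loading at least 1.5-fold lower, or higher, in each passage, with genes that went opposite ways as the planned chance level. A library trend shared by both passages would make genes agree, so that level does not cover it.

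Of 25 gene lists, 23 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists. They held OXPHOS complex I, OXPHOS complexes II to V, mitochondrial and cytosolic ribosomal proteins, translation initiation factors, chromatin regulators, pluripotency genes and markers of neuroectoderm, endoderm, and trophectoderm and amnion. Others were fibroblast (feeder) markers, the interferon response, integrated stress response and unfolded protein response, p53 targets, mRNAs reported as DAP5 targets, apoptosis regulators, G1/S and G2/M genes, replication-dependent histones, noncoding and nuclear RNAs, immediate early genes, and hypoxia and glycolysis genes. The mesendoderm and mesoderm list had 4 tested members and was not tested, and none of the 13 mitochondrially encoded mRNAs was analysed here. With the values as deposited, no list call in any of the 4 contrasts held when camera estimated the correlation between members, and that adjusted p is given beside each call.

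Genes were named by a fixed rule. EIF4G2, EIF4G1, EIF4G3 and HMGN3 were named in every contrast. Of called genes with the same sign in both passages and a mean of at least 50, the 12 highest and 12 lowest log2 changes were named (5 and 5 in shNT cells), filled by smallest raw p where fewer were called. Up to 3 members per list with the smallest raw p could be named too, and symbols of uncharacterised genes were skipped.

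The labels tie the replicate letters to passages 51 and 53, so libraries of one letter share a passage. Deviations from the group means correlated at 0.0145 to 0.31 over the 6 pairs of groups. The highest were 0.31 and 0.22, between total and polysome libraries of shDAP5 and of shNT, followed by 0.209 between the total libraries of both hairpins. The main fit left this pairing out, and a fit with culture as a block, which takes it in, is given for loading. The fit with passage as a block is given beside a result where it changed a call. The labels do not say whether the passages were separate transductions, so p-values measure only the spread between these samples. Replicates of a group correlated at 0.9822 to 0.9917 on the log2 scale and differed beyond sampling noise, with a chi-square per degree of freedom of 4.631 to 15.44.

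The tests were tried on simulated reads for the 12387 genes, with 200 changed genes per contrast. For total RNA limma found 46.3% of genes changed 1.5-fold, 83.6% at 2-fold and 98.5% at 4-fold. For loading it found 10.4%, 59.7% and 90.9%. Unchanged genes called numbered 8 and 10. A list lowered by 0.38 (log2) in loading was recovered at -0.37 with 0 of the other lists called. Simulated genes were drawn independently and, in that step, without a GC trend. False list calls caused by correlated members or by such a trend were therefore not tried.

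The other settings tried were another pseudocount, filter and scaling, a passage block, a culture block, smaller fits, eBayes without trend, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, leaving out each library, and for lists fry, a rotation test. Corrections for GC content and coding length were added after seeing the data. Each library's smooth trend (loess, span 0.3) was subtracted there.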

Results

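The 8 libraries measured mRNA in human embryonic stem cells with a control hairpin or a DAP5 knockdown, in total RNA and in the heavy polysome fractions, where mRNAs carry many ribosomes. DAP5 is a relative of the translation initiation factor eIF4G that lacks the part binding the cap-binding protein. The total libraries held 12646710 and 12169293 recovered reads for shNT and 8768586 and 9613698 for shDAP5, in passages 51 and 53. The polysome libraries held 14066869 and 13211208 for shNT and 5165907 and 19094260 for shDAP5. In every library between 15383 and 16652 genes had a read. Values are normalised read counts, given as mean ± SD (n = 2) per group.

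The targeted gene was measured first. EIF4G2 stood at 25810 and 24950 in the shNT total libraries and at 5759 and 5984 in those of shDAP5. In heavy polysomes it stood at 26210 and 28860 in shNT and at 4269 and 4687 in shDAP5. The shDAP5 level was 23.1% of that in shNT in total RNA (95% interval 19.4 to 27.5%) and 16.3% in heavy polysomes (13.7 to 19.4%). The log2 change was -2.11 (SE 0.12, limma adjusted p = 3.1e-07) in total RNA and -2.62 (SE 0.12, adjusted p = 3.5e-08) in heavy polysomes. By this gene all 8 libraries went with their hairpin labels. Its shNT values were similar in both fractions, so it checks neither the fraction labels nor a small admixture of the other hairpin. EIF4G1, which encodes the canonical scaffold factor eIF4G, was at 1870 ± 319 in shNT and 4100 ± 256 in shDAP5 heavy polysomes, a rise of 1.14 (log2, SE 0.13, limma adjusted p = 5.6e-05). In total RNA its change was 0.31 (adjusted p = 0.13 in limma, 0.047 with passage as a block). EIF4G3, another member of the family, was not called in total RNA (-0.22, adjusted p = 0.28 in limma) or in heavy polysomes (-0.01, adjusted p = 0.97).

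**Figure D1:**
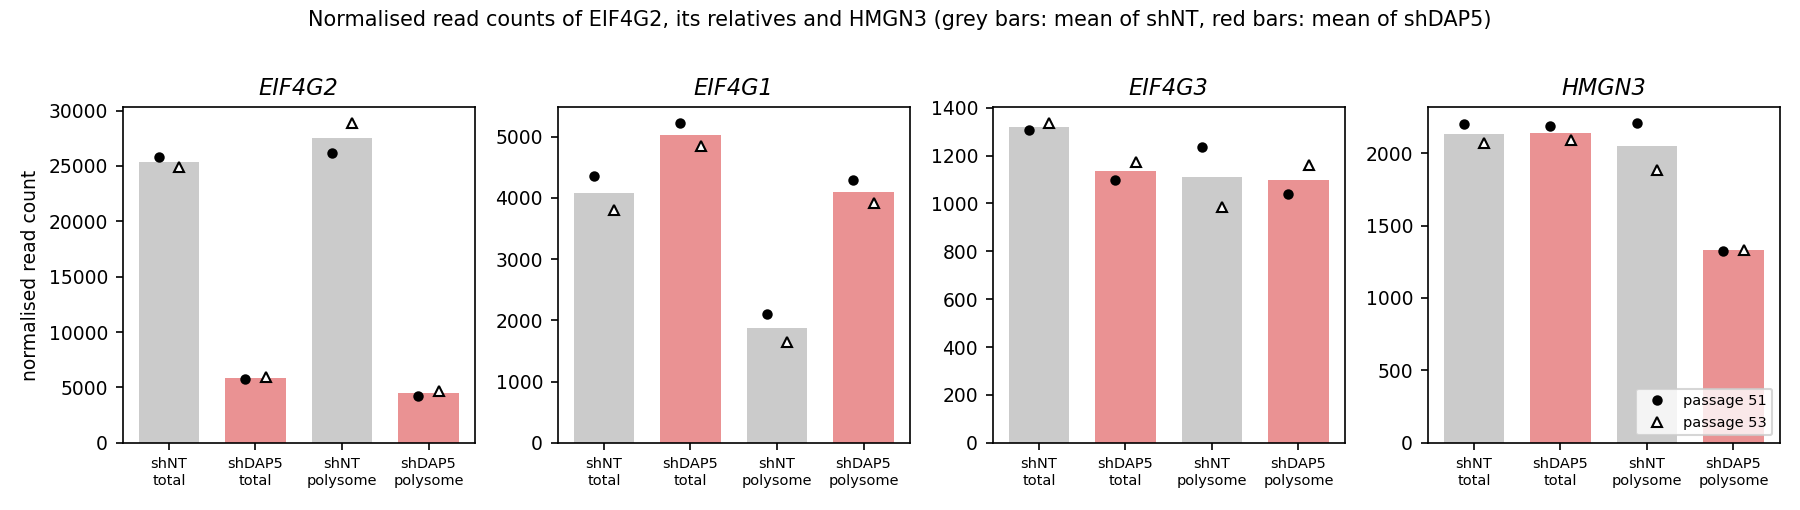
Normalised read counts of EIF4G2, EIF4G1, EIF4G3 and HMGN3 (vertical axes, linear from 0, 1 scale per gene) in the 4 groups; bars are means, filled circles passage 51 and open triangles passage 53. EIF4G2 lies between 4269 and 5984 in the shDAP5 libraries and between 24950 and 28860 in the shNT libraries, while HMGN3 is lower in the shDAP5 polysome libraries (1330 ± 4.87) than in the other groups.

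The comparison of total RNA asked which mRNAs changed in abundance on knockdown. A set of genes near the detection limit in shNT cells was expressed in shDAP5 cells. ZNF560, a zinc finger gene, had 0 reads in both shNT libraries and a value of 159 ± 0.892 in shDAP5, at least 65.4-fold higher against a floor of 3 reads per library. The other large rises were in ZNF528, ZNF229, the homeobox genes GBX2 and PAX6, DPPA3, the proteasome assembly factor PSMD5, NLRP7, VAV1, ZFP3, GNA14 and PIWIL2, of the germline piRNA pathway. PSMD5 went from 4.48 ± 1.8 to 176 ± 42.2, PAX6 from 14.2 ± 2.63 to 352 ± 104 and NLRP7 from 26.8 ± 0.703 to 701 ± 195. Of the 12 largest falls, the most abundant was SFRP1, a secreted WNT antagonist, from 9180 ± 978 to 1440 ± 514 (log2 change -2.71, SE 0.30, limma adjusted p = 5.2e-05). The WNT receptor FZD2 fell from 276 ± 28.7 to 44.1 ± 0.286, and ABCA5, SEMA6D, SHISA3, COL9A1, CA11, TRPC4, FEZF1, PLCL2, CBLN1 and PRTG fell by log2 changes between -3.17 and -2.35. HMGN3, a nucleosome-binding protein whose mRNA is reported as a DAP5 target, was at 2130 ± 92.5 in shNT and 2140 ± 68 in shDAP5 (log2 change 0.00, SE 0.12).

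With limma, 1195 of the 12387 genes were higher and 1103 lower in shDAP5 total RNA, and 746 of these 2298 differed at least 2-fold. Without 1 of the total libraries the count was 951 (shNT, passage 51), 965 (shNT, passage 53), 1288 (shDAP5, passage 51) or 944 (shDAP5, passage 53).

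Among the lists, genes of the integrated stress response, which ATF4 induces on amino acid shortage, had the lowest median of the 23. Of 29 members 19 fell and 0 rose (22 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.3e-09, adjusted p = 0.14 with an estimated correlation). The asparagine synthetase gene ASNS fell by 1.5 on the log2 scale, the serine synthesis gene PSAT1 by 1.2 (9480 ± 210 to 4140 ± 355) and the cystine transporter SLC7A11 by 1.04. Pluripotency genes had a median of 0.26, with 14 of 31 higher and 2 lower (14 and 3 adjusted over the list alone; camera adjusted p = 0.00019, adjusted p = 0.39 with an estimated correlation). GDF3, a TGF-beta family ligand, rose from 49.4 ± 10.7 to 415 ± 73.8, DPPA2 from 83 ± 22 to 410 ± 0.15 and UTF1 from 6.48 ± 1.04 to 92.8 ± 17.3. Hypoxia and glycolysis genes had a median of 0.33, with 14 of 30 higher and 2 lower (15 and 3 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.41 with an estimated correlation). The mitophagy receptor BNIP3 rose from 283 ± 17.1 to 1940 ± 86.1, and the glycolytic LDHA and HK1 rose by 1.01 and 0.93 (log2).

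Lists of the energy and protein synthesis machinery moved up by small amounts in total RNA. OXPHOS complex I had a median of 0.25 with 6 of 38 members higher (6 adjusted over the list alone; camera adjusted p = 0.00078, adjusted p = 0.14 with an estimated correlation). For OXPHOS complexes II to V it was 0.26 with 12 of 41 higher (16 adjusted over the list alone; camera adjusted p = 1.7e-05, adjusted p = 0.37 with an estimated correlation), among them SDHB at 0.83. Mitochondrial ribosomal proteins had a median of 0.25 with 12 of 76 higher (6 adjusted over the list alone), and cytosolic ribosomal proteins one of 0.20 with 9 of 80 higher (1 adjusted over the list alone). Both had a camera adjusted p = 2.5e-05 (adjusted p = 0.41 and 0.45 with an estimated correlation). In these 4 lists 0 members fell. Replication-dependent histones had a median of 1.28 with 3 of 6 higher (3 adjusted over the list alone; camera adjusted p = 0.0029, adjusted p = 0.41 with an estimated correlation), led by HIST1H2BK at 2.16. Only 6 of 58 listed histone genes passed the filter in these libraries of polyadenylated RNA. The median does not stand for the whole family, whose near-identical copies make its values uncertain too.

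Some list calls in total RNA were lost without 1 library. Fibroblast (feeder) markers had a median of -0.41, with 5 of 16 lower and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.41 with an estimated correlation), and COL1A2 fell by 1.14. Without the shDAP5 library of passage 51 that median was -0.28 (adjusted p = 0.094), and without the shNT library of passage 53 it was -0.46 (adjusted p = 0.052). Unfolded protein response genes had a median of -0.30 with 1 of 19 lower (1 adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.56 with an estimated correlation). Their adjusted p was 0.22 without the shDAP5 library of passage 51 (median -0.20) and 0.27 without the shNT library of passage 53 (-0.25). p53 targets had a median of 0.24 with 5 of 24 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.048, adjusted p = 0.5 with an estimated correlation). ZMAT3 rose by 1.5 and PHLDA3 by 1.06, and the list's adjusted p was 0.12 without the shDAP5 library of passage 53 (median 0.19), 0.15 without the shNT library of passage 51 (0.25) and 0.053 with libraries scaled to equal totals.

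Cell cycle lists were lower in total RNA, with a median of -0.17 for G1/S genes (1 of 24 lower, 1 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.56 with an estimated correlation) and -0.18 for G2/M genes (1 of 28 lower, 0 adjusted over the list alone; camera adjusted p = 0.028, adjusted p = 0.64 with an estimated correlation). Without the shDAP5 library of passage 51 the adjusted p was 0.094 (G1/S, -0.16) and 0.25 (G2/M, -0.15). With GC content and coding length corrected it was 0.053 for G2/M (-0.15), and 0.057 with passage as a block and a GC correction, where the median stayed at -0.18. It was 0.15 for G1/S (-0.11) without the shNT library of passage 51 and 0.093 for G2/M (-0.19) without that of passage 53. By fry, a rotation test, the unfolded protein response (adjusted p = 0.15), p53 targets (0.079), G1/S (0.15) and G2/M genes (0.21) were not called, and apoptosis regulators were called higher (0.046). The other 10 lists were not called (camera adjusted p 0.062 to 0.89): initiation factors, chromatin regulators, the neuroectoderm, endoderm, and trophectoderm and amnion markers, the interferon response, reported DAP5 targets, apoptosis regulators, noncoding RNAs and immediate early genes. Their members went both ways. The immediate early gene JUN rose by 1.06 and EGR1 fell by 1.2. Among the reported DAP5 targets MYC rose by 0.79 and BCL2 fell (log2 change -1.12). That call of BCL2 was lost without any 1 of the total libraries. The trophectoderm marker TFAP2A fell from 49.9 ± 3.19 to 3.45 ± 3.37. Median and mean differed in sign for endoderm (-0.14 and 0.32) and noncoding RNAs (-0.10 and 0.15).

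In heavy polysomal RNA the same contrast asked which mRNAs changed among those on many ribosomes. ZNF560, ZNF528, PSMD5, DPPA3, ZNF229, GNA14, GBX2, VAV1, UTF1 and PAX6 were again among the 12 largest rises, joined by HSPB2 and by the readthrough transcript HNRNPUL2-BSCL2. PSMD5 was at 7.61 ± 4.54 in shNT and 219 ± 5.43 in shDAP5, UTF1 at 11.6 ± 3.97 and 141 ± 2.6. ZNF229 lost its call without the shDAP5 polysome library of passage 53 (log2 change 3.47, limma adjusted p = 0.063). SFRP1 fell from 11800 ± 1040 to 1720 ± 969, and TRPC4, SEMA6D, ABCA5, TM4SF18, CUZD1, SHISA3, SGMS2, CA11, COL9A1, CYP2U1 and TMSB15A, which has a near-identical copy, fell by log2 changes between -3.39 and -2.43. HMGN3 was at 2050 ± 226 in shNT and 1330 ± 4.87 in shDAP5 heavy polysomes, a log2 change of -0.62 (SE 0.12, limma adjusted p = 0.0012). With GC content and coding length corrected that change was -0.21 (adjusted p = 0.15).

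By limma 2354 genes were higher and 2533 lower in shDAP5 heavy polysomes, and 1254 of these 4887 differed at least 2-fold. The fit shared 1 error estimate per gene between the fractions. Replicates differed more in polysomes (median absolute log2 difference 0.2 in shNT and 0.227 in shDAP5) than in total RNA (0.124 and 0.145). With only the libraries compared, 3854 genes were called in heavy polysomes and 3808 in total RNA. The larger count in heavy polysomes is therefore no measure of a wider effect there. Across genes the change in heavy polysomes had a Spearman correlation of 0.494 with GC content. The difference between passages 51 and 53 correlated with GC content too, at -0.368 in shNT and 0.406 in shDAP5 polysomes. With a GC correction 3899 of 11843 genes with GC values were called, 2801 of them among the 4887. Of the genes higher in total RNA, 902 were also higher in heavy polysomes (227.1 for independent lists), and of those lower, 891 were also lower (225.6). Genes called in opposite directions numbered 4 and 0. Across genes, which are not independent replicates, the log2 changes of both fractions had a Pearson r of 0.794 (Spearman 0.708). With total RNA of one passage set against polysomes of the other, r was 0.791 and 0.6. The fractions share no library but come from the same cultures. Of the polysome libraries, that of shNT passage 51 held 239.8 summed over 22 genes found at 5 or less in shNT total RNA and at 30 or more in that of shDAP5, a set chosen after seeing the values, against 33.47 in passage 53. Leaving it out gave 3333 calls.

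**Figure D2:**
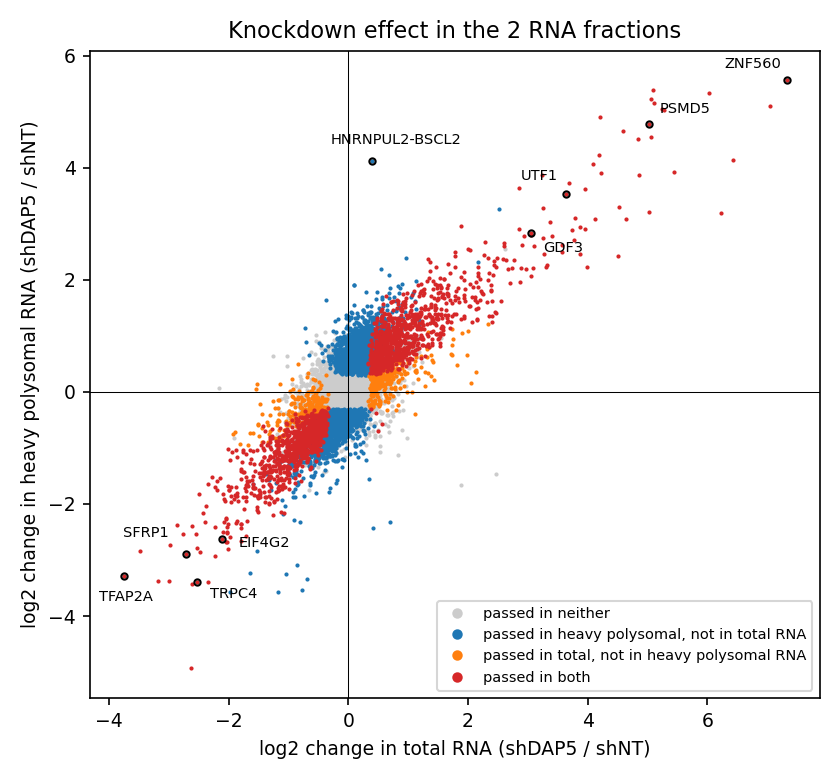
Log2 change (shDAP5 over shNT) of each of the 12387 tested genes in total RNA (horizontal axis) and in heavy polysomal RNA (vertical axis), coloured by limma adjusted p under 0.05. Of the called genes, 902 were higher and 891 lower in both fractions, and HNRNPUL2-BSCL2 lies far above the diagonal. Fitted values of genes with 0 to 3 reads in shNT, such as ZNF560, depend on the pseudocount.

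Pluripotency, hypoxia and stress response lists moved in heavy polysomes as in total RNA. Pluripotency genes had a median of 0.50, with 17 of 31 higher and 2 lower (18 and 2 adjusted over the list alone), and hypoxia and glycolysis genes one of 0.49, with 17 of 30 higher and 1 lower (18 and 1 adjusted over the list alone). Both had a camera adjusted p = 0.00075 (adjusted p = 0.77 with an estimated correlation). GDF3 rose from 106 ± 18.1 to 764 ± 116, LEFTY2, a NODAL antagonist, from 133 ± 28 to 811 ± 173, and the pyruvate kinase gene PKM2 from 5590 ± 207 to 16800 ± 3680. Integrated stress response genes had a median of -0.47 with 18 of 29 lower (18 adjusted over the list alone; camera adjusted p = 7.7e-05, adjusted p = 0.61 with an estimated correlation), and ASNS fell by 1.90. G2/M genes had a median of -0.40 with 17 of 28 lower and 2 higher (18 and 3 adjusted over the list alone; camera adjusted p = 0.0074, adjusted p = 0.77 with an estimated correlation). TOP2A fell by 1.02 and CENPE by 1.07, and with a GC correction the list's median was -0.16 (adjusted p = 0.12), or -0.19 (0.066) with coding length corrected too.

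Cytosolic ribosomal proteins, higher in total RNA, were lower in heavy polysomes, with a median of -0.23 and 22 of 80 lower against 1 higher (14 and 1 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.78 with an estimated correlation). The call was lost without the shDAP5 polysome library of passage 53 (-0.13, adjusted p = 0.33), with quantile normalization (-0.18, adjusted p = 0.057) and with GC content and coding length corrected (0.01, adjusted p = 0.88). Chromatin regulators had a median of 0.16, with 53 of 162 higher and 22 lower (53 and 25 adjusted over the list alone; camera adjusted p = 0.038, adjusted p = 0.78 with an estimated correlation). The corepressor TRIM28 rose from 3530 ± 341 to 8340 ± 1180 and the histone demethylase KDM5C from 976 ± 21.1 to 2340 ± 11.2. That list's adjusted p was 0.12 without the shDAP5 polysome library of passage 51 (median 0.13), 0.31 without the shNT polysome library of passage 53 (0.05) and 0.052 with a GC correction. By fry the cytosolic ribosomal (adjusted p = 0.072), chromatin (0.12) and G2/M lists (0.075) were not called, while OXPHOS complex I was called lower (0.0064) and immediate early genes higher (0.0061). The other 17 lists were not called (camera adjusted p 0.097 to 0.92). For OXPHOS complex I, 14 of 38 members were lower and 4 higher, and for complexes II to V 15 of 41 were lower and 6 higher. Among the reported DAP5 targets the apoptosis inhibitor BCL2 fell by 1.69 and MYC rose by 0.95. BCL2 was lower in total RNA too (log2 change -1.12), and no member of this list was called in loading over all genes. Median and mean differed in sign for the endoderm, trophectoderm and amnion, fibroblast and interferon lists.

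The loading comparison addressed the question in the series title, which mRNAs lose ribosomes on DAP5 knockdown. It is the change in heavy polysomes minus the change in total RNA. By limma 1 gene passed, HNRNPUL2-BSCL2, with a loading change of 3.72 (log2, SE 0.35, adjusted p = 0.00055). This transcript joins the neighbouring genes HNRNPUL2 and BSCL2, whose reads overlap its own, so its value is uncertain. In total RNA it was at 322 ± 121 in shNT and 414 ± 80.2 in shDAP5, and in heavy polysomes at 9.35 ± 0.476 and 179 ± 5.4. Without the trend in eBayes its adjusted p was 0.11.

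In limma with all 8 libraries and no block, no gene passed for lower loading, while 1814 genes in both directions had an unadjusted p under 0.05. The next smallest adjusted p was 0.13. On the recovered reads edgeR called 1 gene higher and 0 lower, and DESeq2 103 higher and 68 lower, without HNRNPUL2-BSCL2, to which it gave no adjusted p. The largest lower values by p were -1.12 in UQCRH and -0.76 in its near-identical copy UQCRHL, both of respiratory complex III, -1.04 in USMG5 of the ATP synthase, -0.78 in RPL23A and -0.83 in the thioredoxin gene TXN. CCDC72, DYNLL1, ZCRB1, AIDA, EI24, PIP4K2A and the proteasome maturation factor POMP had values between -1.20 and -0.68. On the other side TRIM28 had 1.07, and MYO9B, CDC42BPB, KIF1A, CDK11A (which has a near-identical copy), PRRC2A, STXBP2, DNM2, RANGAP1, NUMA1 and AP3D1 had values between 0.81 and 1.16. All 23 had an adjusted p of 0.13 in limma and of 0.029 to 0.044 with passage as a block. With culture as a block, which pairs the total and polysome libraries of a culture, all 23 were called (adjusted p 0.0002 to 0.012). The 23 were picked by their small p in this contrast, so calls in a refit of the same libraries are no separate evidence. EIF4G1 had a loading change of 0.83 (adjusted p = 0.13, 0.034 with the passage block and 0.0033 with the culture block). HMGN3 had -0.62 (SE 0.17, limma adjusted p = 0.15, 0.021 with the culture block), with -0.73 in passage 51 and -0.52 in passage 53, EIF4G2 had -0.51 (adjusted p = 0.19) and EIF4G3 had 0.21 (adjusted p = 0.62).

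With passage as a block, limma called 96 genes higher and 32 lower in loading. The 96 had a median GC content of 60.3% and a median coding length of 2889 bases, and the 32 had 46.3% and 351 bases. With that block and a GC correction 36 genes were higher and 67 lower, 41 of them among the 128, and with GC content and coding length corrected 1 gene was called. The culture block called 459 genes higher and 252 lower, 66 and 113 with a GC correction, and 9 and 13 with GC content and coding length corrected. In this last fit HMGN3 (-0.24, adjusted p = 0.38) and EIF4G1 (0.46, adjusted p = 0.11) were not called. Of the 23 genes RANGAP1 (adjusted p = 0.043), EI24 (0.023) and PIP4K2A (0.046) were called, and USMG5, without a GC value, was not tested. The others had values between -0.72 (ZCRB1) and -0.25 (POMP) or between 0.34 (AP3D1) and 0.74 (STXBP2). Across genes the loading change had a Spearman correlation of 0.578 with GC content, 0.663 in passage 51 and 0.242 in passage 53. By the size rule, 222 genes were at least 1.5-fold lower in both passages and 373 at least 1.5-fold higher, while 85 and 50 passed in opposite directions. With a GC correction 219 were lower and 134 higher. A GC trend shared by both passages makes genes pass on the same side, so the opposite counts are no chance level for it. The loading changes of both passages had a Pearson r of 0.385 across genes.

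Lists of short mRNAs for mitochondria and ribosomes were lower in loading. Cytosolic ribosomal proteins had a median of -0.41 (camera adjusted p = 4.4e-14, adjusted p = 0.37 with an estimated correlation), OXPHOS complexes II to V -0.44 (adjusted p = 5.8e-09; 0.25 with an estimated correlation), OXPHOS complex I -0.35 (adjusted p = 1e-06; 0.08 with an estimated correlation) and mitochondrial ribosomal proteins -0.21 (adjusted p = 0.0016; 0.5 with an estimated correlation). Every median was negative in each passage. Single members called numbered 0 over all genes, and 25, 21, 9 and 0 fell when adjusted over the list alone. RPL32 went from 1960 ± 75 to 2570 ± 144 in total RNA and from 2940 ± 114 to 2370 ± 92.1 in heavy polysomes (loading change -0.70, limma adjusted p = 0.13, 0.044 with passage as a block). By the size rule, 9 of 80 cytosolic ribosomal and 7 of 41 complex II to V mRNAs were lower in both passages (Fisher's exact test over all tested genes, adjusted p = 0.000144 for each), against 3 of 38 for complex I (adjusted p = 0.232), 0 of 76 for mitochondrial ribosomal proteins (adjusted p = 1) and 1.79% of all genes. Fisher's test counts genes as independent draws, which the members of a list may not be. Ribosomal protein genes have many processed pseudogenes, so their reads are uncertain. With GC content and coding length corrected, complex I (-0.17, adjusted p = 0.0045; 0.32 with an estimated correlation) and cytosolic ribosomal proteins (-0.16, adjusted p = 1.8e-05; 0.97 with an estimated correlation) were still called at the preset correlation, and complexes II to V (-0.15, adjusted p = 0.08) and mitochondrial ribosomal proteins (-0.07, adjusted p = 0.76) were not.

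**Figure D3:**
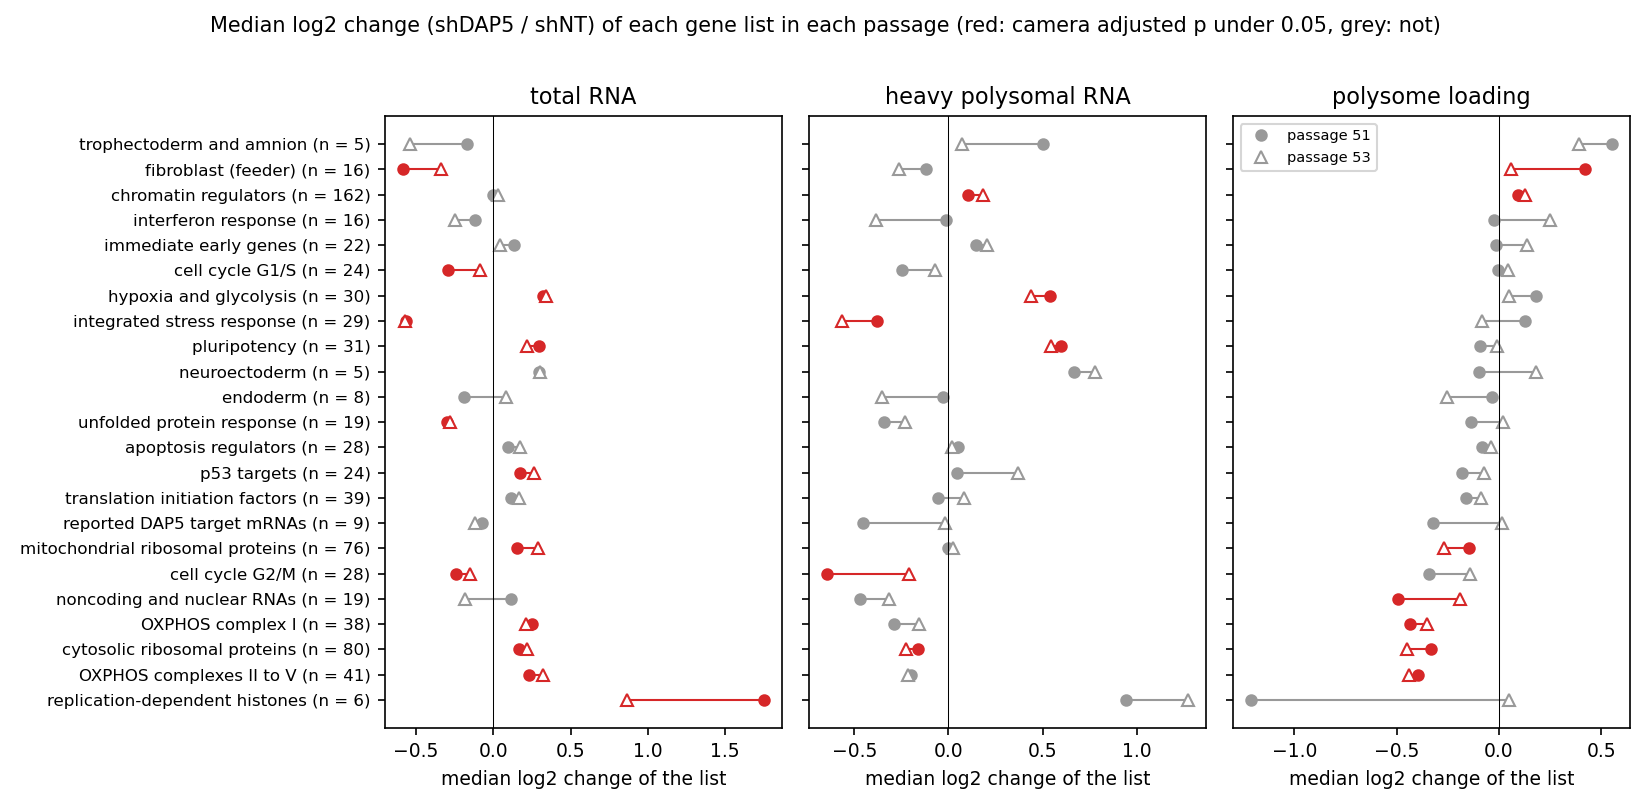
Median log2 change (shDAP5 over shNT, horizontal axes) of the tested members of each of 23 gene lists in total RNA, in heavy polysomal RNA and in loading; filled circles are passage 51, open triangles passage 53, and red marks a camera adjusted p under 0.05 with the preset correlation. The OXPHOS and ribosomal protein lists lie above 0 in total RNA and below 0 in loading in both passages (cytosolic ribosomal proteins 0.20 and -0.41).

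Chromatin regulators had higher loading, with a median of 0.11 (camera adjusted p = 0.005, adjusted p = 0.76 with an estimated correlation), and 15 of 162 were at least 1.5-fold higher in both passages (Fisher's exact test, adjusted p = 0.00258). Here too Fisher's test counted genes as independent. With 0 members called over all genes, 11 were higher and 4 lower when adjusted over the list alone. The adjusted p was 0.12 without the shNT total library of passage 51 (0.06), 0.25 without the shNT polysome library of passage 53 (0.03) and 0.15 with GC content and coding length corrected. Fibroblast (feeder) markers had a median of 0.31 (camera adjusted p = 0.019, adjusted p = 0.47 with an estimated correlation; 1 of 16 higher adjusted over the list alone). Their adjusted p was 0.13 without the shDAP5 total library of passage 51 (0.27), 0.12 without the shNT polysome library of passage 51 (0.13), 0.34 with no filter and 0.31 with a GC correction. Noncoding and nuclear RNAs had a median of -0.31 (camera adjusted p = 0.011, adjusted p = 0.47 with an estimated correlation; 0 of 19 adjusted over the list alone). Theirs was 0.17 without the shDAP5 total library of passage 51 (-0.14) and 0.059 without the shDAP5 polysome library of passage 53 (-0.24). By fry the mitochondrial ribosomal (adjusted p = 0.12), chromatin (0.63), fibroblast (0.19) and noncoding lists (0.26) were not called. The other 16 lists, reported DAP5 targets included (median -0.18), were not called (camera adjusted p 0.077 to 0.96). The median and the direction of the test differed in sign for the pluripotency, neuroectoderm and p53 lists.

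Heavy polysomal against total RNA in shNT cells described what the fraction held without knockdown. Equal totals moved the median of all genes by -0.27 (log2) in this contrast, and changes here are relative to the deposited scaling. SYNC was higher in heavy polysomes (16.5 ± 11.8 to 280 ± 25.4), as were EAF2 and FRG1 by 1.76 and 1.72. GBX2 (2.02) was called too, but not without the shNT polysome library of passage 51 (1.26, limma adjusted p = 0.063). TMOD1 (1.99, adjusted p = 0.041) lost its call without any 1 of the 4 shNT libraries (1.64 to 2.34, adjusted p = 0.07 to 0.23). HNRNPUL2-BSCL2 was lower by a log2 change of -4.91, and PAR5, a noncoding RNA, HSPG2, NR6A1 and ELK3 by changes between -3.12 and -2.32. EIF4G1 was lower by -1.13 (adjusted p = 2.5e-05), and EIF4G2 (0.12), EIF4G3 (-0.26) and HMGN3 (-0.06) were not called. In all 2690 genes were higher and 2346 lower by limma, a share of 53.4% higher, against 25.3% (1402 higher, 4140 lower) with equal totals. Without the shNT total library of passage 51 or 53, 3072 or 3293 genes were called.

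Noncoding and nuclear RNAs were lower in shNT heavy polysomes, with a median of -1.17 and 15 of 19 lower (15 adjusted over the list alone; camera adjusted p = 6.8e-07, adjusted p = 0.19 with an estimated correlation), such as the snoRNA host gene SNHG5 at -1.76. Mitochondrial ribosomal proteins had a median of 0.60 with 47 of 76 higher and 1 lower (49 and 2 adjusted over the list alone; camera adjusted p = 8.6e-12, adjusted p = 0.19 with an estimated correlation), and OXPHOS complex I 0.39 with 20 of 38 higher and 1 lower (21 and 1 adjusted over the list alone; adjusted p = 4e-05, 0.14 with an estimated correlation). OXPHOS complexes II to V had 0.35 with 20 of 41 higher and 3 lower (20 and 3 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.54 with an estimated correlation). Initiation factors had 0.52 with 22 of 39 higher and 7 lower (23 and 8 adjusted over the list alone) and cytosolic ribosomal proteins 0.33 with 42 of 80 higher and 11 lower (43 and 12 adjusted over the list alone), both at a camera adjusted p = 0.0018 (adjusted p = 0.74 with an estimated correlation). With quantile normalization complexes II to V, initiation factors and cytosolic ribosomal proteins were not called (adjusted p = 0.2, 0.57 and 0.67), and the median of the cytosolic ribosomal proteins was -0.02. G1/S genes had 0.42 with 13 of 24 higher and 4 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.74 with an estimated correlation), and an adjusted p of 0.055 with passage as a block. It was 0.57 with quantile normalization (0.13), 0.053 with a GC correction (0.30), 0.1 with GC content and coding length corrected (0.23), 0.087 at a mean of at least 100 and 0.06 with only the libraries compared (0.42 for both). That adjusted p was 0.056 without either shDAP5 polysome library (0.42), 0.099 without the shNT total library of passage 53 (0.39) and 0.22 without the shNT polysome library of passage 51 (0.29). Chromatin regulators had a median of -0.21 with 57 of 162 lower and 35 higher (58 and 36 adjusted over the list alone; camera adjusted p = 0.05, not under the threshold, 0.033 with passage as a block and 0.74 with an estimated correlation). By fry hypoxia and glycolysis (adjusted p = 0.016), endoderm (0.037), unfolded protein response (0.047) and apoptosis genes (0.047) were called higher. The other 15 lists were not called (camera adjusted p 0.05 to 0.86), and median and mean differed in sign for the neuroectoderm (0.07 and -0.06) and the trophectoderm and amnion (0.16 and -0.01) lists.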

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

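The tests of explanations in this part were all chosen after the loading results were seen. The results listed here were singled out because the effect of the knockdown differed between total and heavy polysomal RNA by the interaction test.

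The 4 lists with lower loading were OXPHOS complex I (-0.35), OXPHOS complexes II to V (-0.44), mitochondrial ribosomal proteins (-0.21) and cytosolic ribosomal proteins (-0.41), whose members have short coding regions and took, together, a median of -0.36 ± 0.307 (SD over 234 genes with GC values). A GC trend of the libraries is argued against as the cause, since the median was -0.32 ± 0.271 after its removal and all 4 lists were still called with passage as a block (largest adjusted p 1.6e-05 at the preset correlation; without the block and with an estimated correlation 0.03, 0.11, 0.4 and 0.12). A coding length trend cannot be told apart from another cause and may account for much of it. Removing GC and length trends took the joint median to -0.14 ± 0.212. It ended the calls of complexes II to V (-0.43 ± 0.315 to -0.15 ± 0.196) and mitochondrial ribosomal proteins (-0.21 ± 0.296 to -0.07 ± 0.21) as their medians moved toward 0. Complex I (-0.17 ± 0.171) and cytosolic ribosomal proteins (-0.16 ± 0.217) stayed called by camera at the preset correlation. They were not called at an estimated one (camera adjusted p = 0.32 and 0.97). Both medians were smaller in size than the SD, but that SD is the spread over the members and no error of the median. On the other side, complex I and cytosolic ribosomal proteins lay at or below percentile 0.35, and the other 2 lists at or below percentile 1.69, of 10000 random lists drawn as independent genes and matched on coding length, GC content and mean value (medians -0.20, -0.18, -0.26 and -0.14 for complex I, cytosolic ribosomal proteins, complexes II to V and mitochondrial ribosomal proteins). Heavy fractions taken at different points of the gradient cannot be told apart from a knockdown effect. The slope of polysome minus total on coding length differed between hairpins by 0.106 and between passages of a hairpin by up to 0.067. In passages 51 and 53 this slope was -0.138 and -0.205 in shNT and -0.0481 and -0.0832 in shDAP5. The hairpins thus differed the same way in both passages, but 2 cultures against 2 allow no exact p under 0.33. An effect of DAP5 loss on short mRNAs stays open and was not tested apart from such a difference of the gradients.

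The readthrough HNRNPUL2-BSCL2 had a loading change of 3.72, the only one called in limma with all 8 libraries and no block (128 genes were called with passage as a block, 711 with culture as a block and 171, without this one, with DESeq2), at 9.015 and 9.688 in the shNT polysome libraries and 175.2 and 182.8 in those of shDAP5. Reads divided differently between it and its member genes stay open. Summed over the readthrough, HNRNPUL2 and BSCL2 the loading change was 0.26 (0.21 in passage 51 and 0.32 in passage 53), but the members would have had to gain about 170 in shNT polysomes, less than the SD of 436 of their sum there. A different transcript made or kept in shDAP5 polysomes was not tested.

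Chromatin regulators had a loading change of 0.11 and fibroblast (feeder) markers of 0.31. Noncoding and nuclear RNAs had one of -0.31. None was called with an estimated correlation (camera adjusted p = 0.76, 0.47 and 0.47). Leaving out certain single libraries, named with the loading results, ended the calls, with medians as small as 0.03, 0.13 and -0.14. A GC correction took the fibroblast list to 0.14 (adjusted p = 0.31).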

How the results depend on the processing

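The corrections for GC content and coding length were chosen after seeing the data, the other settings not. EIF4G2 in total RNA kept its direction and call under every setting. For loading, the count of 1 became 128 with the replicate block (96 higher), 711 with a block by culture (459 higher, 252 lower), 179 and 22 with that block and a GC or both corrections, 171 with DESeq2, which gave no adjusted p for 6004 genes, 0 without trend, 103 with the replicate block and a GC correction (36 higher, 67 lower), and 1 to 192 with 1 library left out. Of total RNA the count of 2298 became 3808 with only the libraries compared, 3658 with the replicate block and GC correction, 3835 with the replicate block and both corrections, and 944 to 2751 with 1 library left out. Leaving out 1 library gave 3333 to 4820 calls in heavy polysomes and 3072 to 5515 for the shNT fractions. It leaves 1 library in its group, assumed to vary like the others. The list calls of all 3 knockdown comparisons (13, 6 and 7) became 0 with an estimated correlation. For loading, fry called 3, and the corrections for GC content and coding length left 2, with either block or none. With 1 library left out, 9 to 14, 5 to 6 and 6 to 8 lists were called, and EIF4G2 in total RNA changed by -2.14 to -2.08. The size rule (222 lower, 373 higher) gave 811 and 916 with no filter, where genes going opposite ways rose from 85 and 50 to 689 and 528, 103 and 205 at a mean of at least 100 (6 and 4), and 25 and 36 at 2-fold (15 and 4). It gave 219 lower and 134 higher with a GC correction (77 and 34), and 143 lower and 86 higher with both corrections (68 and 39). It gave 258 lower and 513 higher with the hairpins paired across passages (70 and 71). It needs every library, so none could be left out, and DESeq2 gives no list test. Directions turned for cytosolic ribosomal proteins in heavy polysomes (0.0133 with both corrections, with or without the replicate block) and in the shNT fractions (-0.0243 with quantile normalization), and in the shNT fractions for EIF4G2 (-0.50 with quantile normalization) and EIF4G3 (0.38 with both corrections, with or without the replicate block). The replicate block changed no call named here other than those given with the comparisons. Over all settings the named genes kept direction and side of the threshold in 3433 values, lost the call in 35 and gained it in 161. Lists did so in 687 and lost it in 105. With edgeR 2522, 4825, 1 and 5311 genes were called in total RNA, heavy polysomes, loading and the shNT fractions. The cause was not tested. Depth limits the low genes most in the shDAP5 polysome library of passage 51.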

Other observations

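The tests in this part were chosen after the values were seen.

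Expression that was nearly absent in shNT cells and present in shDAP5 cells was one-sided. All 18487 genes were searched, with no filter on the mean and leaving out XIST and genes of the Y chromosome. Of these, 22 were at 5 or less in both shNT total libraries and at 30 or more in both of shDAP5. The reverse was seen for 1 gene, CNRIP1 (34.49 and 40.23 in shNT, 4.669 and 1.072 in shDAP5). The 22 included the cancer-testis antigen genes MAGEA2, MAGEA3 and MAGEA6, which share reads with near-identical copies, the germline genes TDRD1 and RBM46, the zinc finger genes ZNF560, ZNF528, ZNF229 and ZNF662, the homeobox genes HOXB2 and GBX2, the neural transcription factor gene OLIG3 and the protocadherin gene PCDHA1. ZNF662 was at 84.03 and 66.46 in shDAP5 total RNA against 2.406 and 4.105 in shNT, TDRD1 at 79.36 and 91.11 against 4.01 and 4.927, and C9orf64 at 234.6 and 259.4 against 3.208 and 2.463. In shDAP5 heavy polysomes the 22 summed to 1728 and 1931, against 1678 and 1865 in total RNA. By chromosome, the median log2 change in total RNA lay between -0.09 (chromosome 18) and 0.13 (chromosome 19, 862 genes). The genes of chromosome 18 had a median GC content of 44.3% and those of chromosome 19 one of 59.3%. Across genes the change in total RNA had a Spearman correlation of 0.142 with GC content, and chromosome and GC content were not separated.

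The same 22 genes summed to 239.8 in the shNT polysome library of passage 51, 13.1% of their level in shDAP5, and to 33.47 (1.83%) in that of passage 53, with 20 of the 22 over double the passage 53 value. Reads exchanged at one rate over the lane are argued against by the 1.83% of the other polysome library, which played no part in the choice of the genes. shDAP5 cells in the shNT culture of passage 51 stay open: 28 genes chosen by the same limits in the libraries of passage 53 alone stood at 5.4% of the shDAP5 level in the shNT total library of passage 51 and at 14.1% in its polysome library, and the ratio of 38.2% (bootstrap 95% interval 20.3 to 58.4%) lay neither under the limit of 1/3 set for excluding them nor near 100%. RNA or reads of shDAP5 polysomes carried into this 1 library may account for it but cannot be told apart from other passage differences: genes 2-fold to 8-fold higher in shDAP5 total RNA were shifted by 0.25 ± 0.027 (bootstrap SE) in passage 51 against 53, where the carried share predicts 0.23, those at least 4-fold higher by 0.68 ± 0.057 (predicted 0.5) and those at least 2-fold lower by -0.11 ± 0.021 (predicted -0.10), while between the shDAP5 libraries the first and last of these sets were shifted by -0.08 ± 0.022 and 0.082 ± 0.033. No biological explanation was tested.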
